A study of Arabidopsis thaliana with 6 samples.

How the data were processed

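Counts of RNA sequencing reads from Arabidopsis thaliana seedlings, aged 4 days by their labels, were compared between the wild type and the mutant pp7l-1. Each genotype had 3 libraries, made from total RNA. The seedlings had grown on agar with sucrose in long days, and the library kit was Illumina TruSeq, per the labels' protocols. Trimmomatic, FastQC, TopHat2 2.1.1 and featureCounts were named as tools, and TAIR10 as the genome build, per the submitters' processing notes. Which annotation was counted, and how the counter treated strand, overlapping genes and reads with several matches, is not given in the sources used here.

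The authors deposited 1 table per library with a count of reads for each of 33341 genes, not normalised. The values were whole numbers and summed to between 11269557 and 16744328 per library. In all 6 libraries 4682 genes had a count of 0. Of the gene codes, 33056 were matched by code to the RefSeq annotation of the assembly TAIR10.1, from which symbols, gene types and coordinates were taken. The remaining 285 codes belonged to 133 plastid and 152 mitochondrial genes. Names of plastid genes came from the gene lists described below, since the annotation did not pair these codes with names. Coordinates are those of TAIR10.1, while the build named by the submitters is TAIR10.

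Among 4 pairs of genes on opposite strands that shared over 90% of their exon bases with each other, the smaller total count was more than 0.8 of the larger in 3. Reads from such pairs therefore cannot be assigned to a strand here, and overlapping genes are uncertain. Of the tested genes, 3002 shared more than 10% of their exon bases with another counted gene. Reads of near-identical copies, as in the LHCB1, RBCS, cruciferin, seed albumin and lipid transfer protein families, may have been split between copies or dropped by the authors' counting.

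From the deposited counts, genes were filtered with edgeR's filterByExpr (minimum count 10), which left 18115 genes. Library sizes were scaled by the trimmed mean of M values (TMM), and the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 was fitted with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. The common biological coefficient of variation was 0.196. Levels are given as CPM (counts scaled to a library of 1e+06), as mean ± SD over 3 libraries, and fold changes as log2 values ± standard error. Where all libraries of a group had a count of 0, the fold is a lower bound against a floor of 3 counts over the group, and where a group had 1 to 3 counts the ratio is given with an exact 95% interval. Floors and intervals cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules.

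Before the data were examined, 26 gene lists were fixed, and all genes encoded in mitochondria were added as a class. Genes with a transposon word in their product name were also added, and are called transposable element genes here. They need not be transposable elements, since no tested gene had that gene type. The 26 lists were the PP7 and plant mobile domain family, light-harvesting antenna, nuclear photosystem and electron transport subunits, Calvin-Benson cycle, chlorophyll biosynthesis, nuclear-encoded plastid ribosomal proteins, plastid transcription machinery, light signalling and chloroplast regulators, 3 classes of plastid genes, anthocyanin and flavonoid pathway, heat shock, oxidative and mitochondrial stress, abscisic acid, salt and cold response, silenced loci, silencing machinery, DNA damage, cell division, circadian clock, defence, root, stomatal and shoot meristem markers, seed storage and embryo markers, and the glyoxylate cycle with lipid mobilisation. The 27 lists with at least 3 tested members were tested against all other genes with camera of limma 3.58.1 (preset correlation 0.01), with adjustment over the lists. Camera with an estimated correlation, and fry, which asks whether the genes of a list move one way on balance, were run beside it. Transposable element genes were also compared with Fisher's exact test, and shares of counts with an exact two-sided permutation test, which with 3 libraries against 3 cannot give a p below 0.1.

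The genes named were chosen by a rule fixed at the same time. It took the tested members of the PP7 family, the 8 highest and 8 lowest log2 fold changes among genes past the threshold with groups that did not overlap and at least 1 CPM in the higher group, the 6 highest and 6 lowest with a symbol and at least 20 CPM, up to 4 members of each list by size of change, or the 2 most abundant where no member passed, and the highest and lowest transposable element genes past the threshold, of which there were 0. Other genes named in the text were chosen after their values were seen.

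Alternatives fixed beforehand were DESeq2 1.42.0, other scalings (RLE, upper quartile, library size alone), no count filter and stricter filters (1 CPM and 10 counts in 3 libraries, or a mean of 5 CPM), the replicate number as a block, leaving out organelle genes, limma voom with and without sample quality weights, glmTreat against 1.2-fold, and leaving out each library in turn. After the data were examined, 3 more were added: leaving out nuclear ribosomal DNA genes and genes within 10 kb of them, nuclear protein-coding genes alone, and leaving out overlapping genes.

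The procedure was tested on simulated data with the means and library sizes of the 18115 genes of this comparison. edgeR recovered 50% of 100 genes changed 2-fold and 91% of 100 genes changed 4-fold, and 7.24% of its calls were false. Changes of 2-fold were thus often missed in this simulation. Only 200 of its genes changed, against 3972 called in the real data, which made its adjusted threshold stricter. Its rates therefore do not give the power of the real comparison. Within each genotype the libraries differed beyond sampling noise, with a chi-square per degree of freedom between 15.0 and 133, so no table is a second count of the same reads. This does not show that the libraries came from separate cultures or RNA samples.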

Results

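Gene expression was measured by RNA sequencing in whole seedlings of Arabidopsis thaliana at an age of 4 days. The question was how the transcriptome of pp7l-1, a mutant of the gene for PROTEIN PHOSPHATASE 7-LIKE (PP7L), differs from that of the wild type. The series concerns the part PP7L plays in chloroplast development. Each genotype had 3 libraries. The wild-type libraries held 15255214, 16744328 and 14342054 counts, and those labelled pp7l-1 held 11269557, 13724880 and 13329691. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these libraries. The first principal component held 59.1% of the variance of the log levels and separated the genotypes.

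PP7L (AT5G10900, chromosome 5, 3435949 to 3439384 on the minus strand in TAIR10.1) had counts of 24, 22 and 21 in the wild type and of 280, 247 and 315 in the libraries labelled pp7l-1. Its level was 1.69 ± 0.267 CPM (SD, n = 3) in the wild type and 19.2 ± 3.23 CPM in the libraries labelled pp7l-1, a log2 fold change of 3.52 ± 0.22 (adjusted p = 1.39e-07). More reads of the mutated gene go against a reading of the label as a loss of its transcript. The sources used here do not describe the lesion, and counts over whole genes do not show which part of the gene was read. The genotype therefore rests on the labels, and so does every direction given here. The other members of the PP7 and plant mobile domain list did not pass the test. PP7 (AT5G63870), the phosphatase from which PP7L takes its name, was at 7.001 ± 1.26 CPM and 6.49 ± 0.889 CPM. MAIL3 (AT1G48120) had a log2 fold change of -0.03 ± 0.27, MAIN (AT1G17930) of 0.29 ± 0.34, MAIL1 (AT2G25010) of 0.17 ± 0.28 and MAIL2 (AT2G04865) of 0.40 ± 0.33. Of the 6 tested members 1 rose, also when adjusted over the list alone. Camera gave the list an adjusted p of 0.0184, and an adjusted p = 0.190 with an estimated correlation. Since only the mutated gene itself passed, the camera call does not show a change in the rest of the list.

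Transcripts of the plastid genome made up 70.0 ± 2.35% (SD, n = 3) of the counts in the wild type and 60.2 ± 4.42% in the libraries labelled pp7l-1. The plastid gene psbA, for the D1 protein of photosystem II, alone took 48.8 ± 3.05% of wild-type counts and 23.5 ± 4.45% of those labelled pp7l-1. The share of rbcL, for the large subunit of Rubisco, was 7.72 ± 1.74% and 15.7 ± 1.49%, and that of the other plastid genes 13.5 ± 0.866% and 20.9 ± 5.09%. Mitochondrial genes took 0.545 ± 0.0508% and 0.817 ± 0.0701%. In each of these comparisons the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 libraries against 3 allow (adjusted p = 0.133 over 8 measures). These are shares of the same total, so the smaller share of psbA by itself raises the other shares. As shares, the rises, that of mitochondrial genes included, are therefore not separate findings. Scaled by TMM, and so relative to the bulk of genes, the 58 tested mitochondrial genes had a median log2 fold change of 0.49. Of these 19 were higher and 1 lower, while rbcL did not pass that test. Counts of nuclear ribosomal DNA genes stood apart in 1 library, with 11.4% in pp7l-1 replicate 1 and between 0.0660% and 0.206% in the other 5 (exact permutation p = 0.4 between genotypes).

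**Figure D1:**
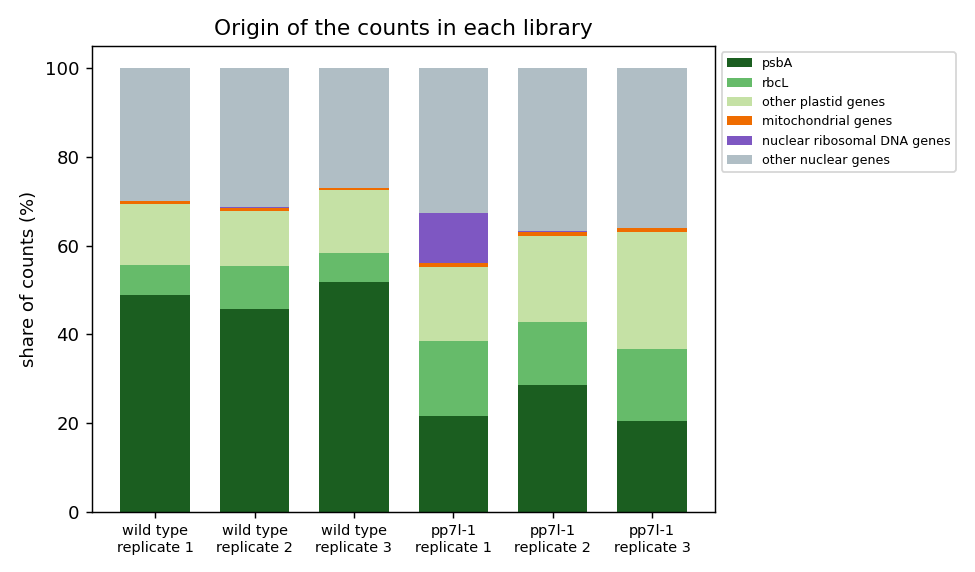
Share of the counts of each library (%) that fell on psbA, rbcL, other plastid genes, mitochondrial genes, nuclear ribosomal DNA genes and other nuclear genes. Each bar is 1 library, and the share of psbA lies between 45.7% and 51.8% in the wild type and between 20.5% and 28.6% in the libraries labelled pp7l-1, and pp7l-1 replicate 1 alone has a visible share of nuclear ribosomal DNA genes.

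Across the genome, 3972 of 18115 genes differed between the genotypes in edgeR's quasi-likelihood test, of which 1929 were higher and 2043 lower in the libraries labelled pp7l-1. A change of more than 2-fold was found in 943 of the higher and 1112 of the lower genes. Among genes with at least 20 CPM and a symbol, the largest rises were in isocitrate lyase (ICL, AT3G21720), cruciferin 3 (CRC, AT4G28520), malate synthase (MLS, AT5G03860), the cruciferin CRA1 (AT5G44120), lipoxygenase 2 (LOX2, AT3G45140), an enzyme of jasmonate synthesis, and the cysteine proteinase CP1 (AT4G36880). LOX2 went from 4.35 ± 0.670 to 57.2 ± 26.8 CPM and CP1 from 2.34 ± 0.488 to 27.8 ± 5.94 CPM. The largest falls of this kind were in BT1 (AT5G63160), a BTB and TAZ domain protein, from 73.7 ± 17.2 to 4.498 ± 1.82 CPM, and in the asparagine synthetase ASN1 (AT3G47340), from 248 ± 127 to 16.6 ± 4.06 CPM. They were followed by the aquaporin PIP2;4 (AT5G60660) with a log2 fold change of -3.83 ± 0.28, the arabinogalactan proteins AGP14 (AT5G56540) with -3.82 ± 0.30 and AGP22 (AT5G53250) with -3.74 ± 0.37 (-4.63 without pp7l-1 replicate 2), and MLP34 (AT1G70850) with -3.34 ± 0.21.

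Several less abundant genes were read in the wild type and not in any library labelled pp7l-1. The MLP-like gene MLP328 (AT2G01520) had 221 counts against 0, at least 81.1-fold lower against a floor of 3 counts over the group. A peptidase gene, AT1G53530, had 128 against 0 (at least 47.0-fold lower), and its neighbour FAP3 (AT1G53520), for a fatty acid binding protein of the chalcone isomerase family, fell from 10.9 ± 0.990 to 0.128 ± 0.175 CPM, where 4 of the 5 counts lay in pp7l-1 replicate 1 and the log2 fold change moved from -6.49 to -8.11 without it. AT4G22510, AT5G04120, AT3G60180 and the snoRNA AT3G08165 also had a count of 0 in the 3 libraries labelled pp7l-1, with 111, 63, 48 and 63 counts in the wild type. The exons of AT4G22510 overlap other counted genes over 90.7% of their length, so its reads are uncertain. The snoRNA AT3G50825 had 125 counts against 1, a ratio of 138 (exact 95% interval 24.3 to 5481), with the 1 count in pp7l-1 replicate 2. In the other direction, AT1G75945 had 1 count in the wild type and 108 in the libraries labelled pp7l-1, a ratio of 98.1 (17.2 to 3909), with the 1 count in wild-type replicate 3, and MPC (AT3G19350) had 3 against 91, a ratio of 27.5 (9.13 to 136). AT2G47780, a rubber elongation factor protein, and AT1G68250 rose by 4.53 ± 0.40 and 4.32 ± 0.35 on the log2 scale, the latter by 5.03 without wild-type replicate 1.

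The number of calls depended on the libraries and on the scaling. Without wild-type replicate 1, 1282 genes were higher and 1434 lower. Without pp7l-1 replicate 1, the library with many ribosomal DNA counts, 1274 were higher and 1397 lower, and without wild-type replicate 3, 1321 and 1384. Scaled on library size alone, 4493 genes were higher and 759 lower (85.6% higher, against 48.6% with TMM), and the median log2 fold change of all genes moved to 0.41. The directions given here are therefore relative to the bulk of genes. Over the lists, camera called 15 of 27, 14 of them higher, the PP7 family with only PP7L past the test included, and 1 lower. With an estimated correlation it called 0, and fry called 15.

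**Figure D2:**
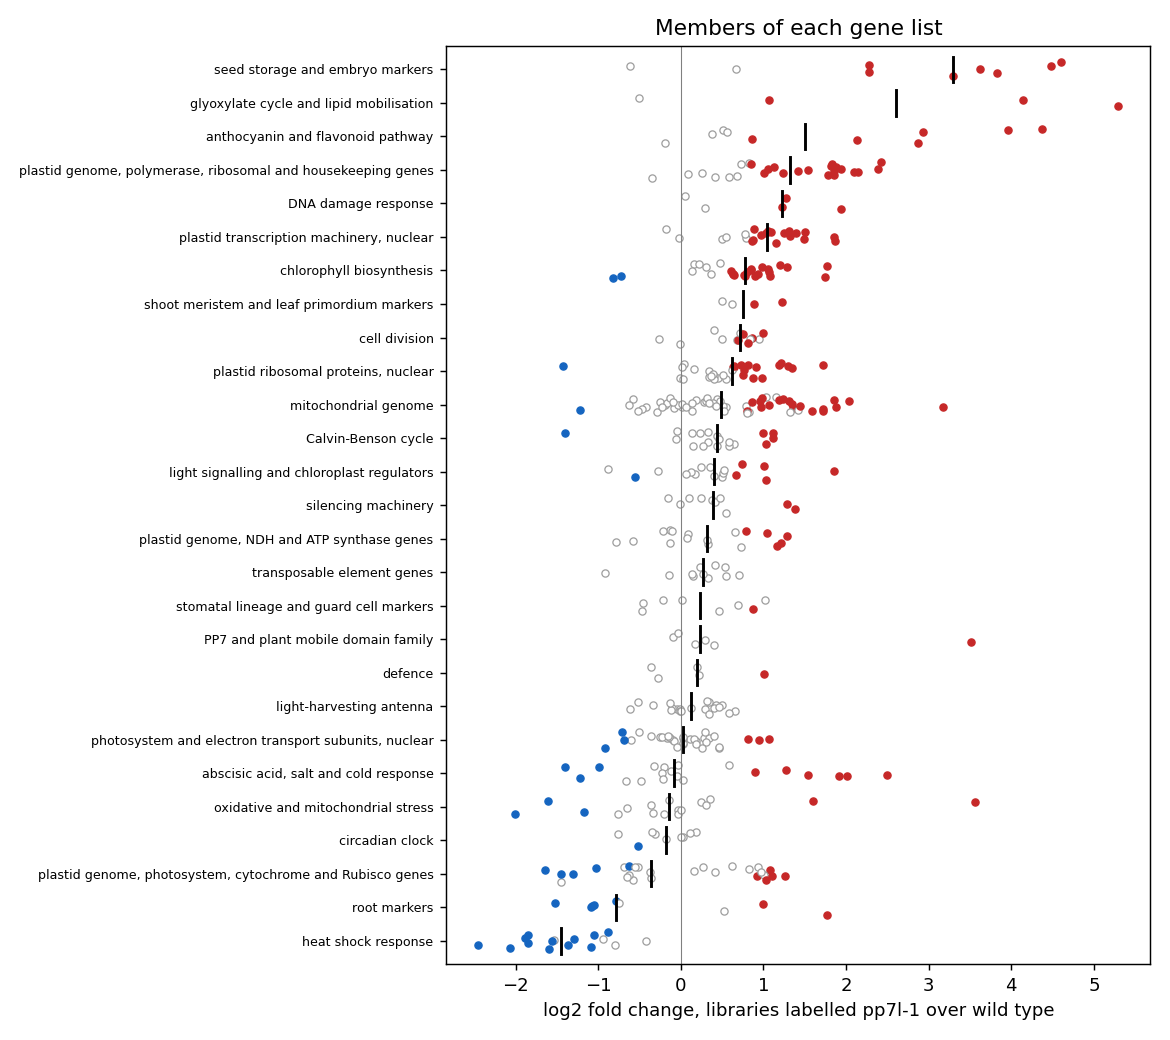
Log2 fold change (libraries labelled pp7l-1 over wild type) of each tested member of the gene lists, ordered by the median, which is drawn as a black bar, with filled points for members past the test over all genes (red higher, blue lower) and open points for the others. Seed storage and embryo markers have the highest median, 3.29 (2.68 without wild-type replicate 1), and heat shock genes the lowest, -1.45 (-2.19 without pp7l-1 replicate 1).

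Of 9 tested seed storage and embryo markers 7 rose and 2 did not pass, 7 also when adjusted over the list alone. CRC rose from 1.66 ± 0.600 to 39.9 ± 24.2 CPM, CRA1 from 1.97 ± 0.209 to 28.2 ± 16.0 CPM, and the 2S albumin gene SESA3 (AT4G27160) from 0.232 ± 0.150 to 5.28 ± 3.03 CPM. The adjusted p of the list was 1.91e-09 with camera and 0.190 with an estimated correlation, and fry gave 0.0349. Without pp7l-1 replicate 3, 12 members could be tested and 11 rose. In the list of the glyoxylate cycle and lipid mobilisation 3 of 4 members rose, 3 also when adjusted over the list alone, where 1 other fell. ICL and MLS, the glyoxylate cycle enzymes by which seedlings turn stored lipid into sugar, rose from 6.33 ± 1.49 to 249 ± 59.0 CPM and from 2.72 ± 0.687 to 47.7 ± 12.4 CPM. PCK1 (AT4G37870), for the gluconeogenic enzyme that follows, rose by 1.07 ± 0.19 on the log2 scale. SDP1, a lipase of oil bodies, had -0.51 ± 0.22 and did not pass over all genes, but without pp7l-1 replicate 3, 1 gene of the list fell. Camera gave an adjusted p of 9.39e-10, which was an adjusted p of 0.0908 with an estimated correlation.

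**Figure D3:**
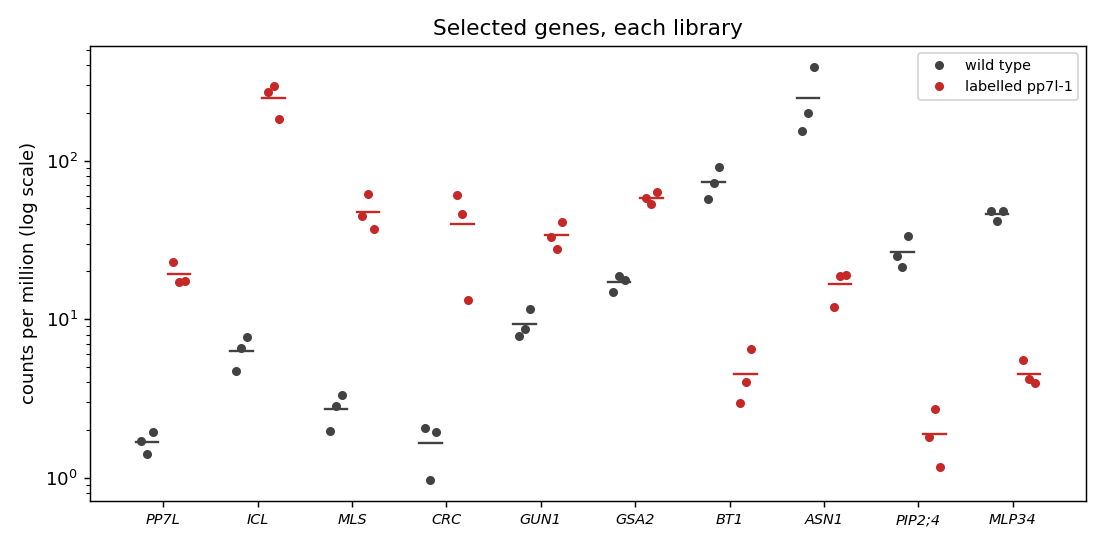
Level of 10 genes in each library (CPM, log scale), with a point per library and a bar for the mean over 3. For each of these genes the groups do not overlap, with PP7L at 1.69 and 19.2 CPM on average and BT1 at 73.7 and 4.498 CPM.

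In chlorophyll biosynthesis 19 of 27 tested genes rose, 2 fell and 6 did not pass, with the same counts when adjusted over the list alone. The glutamate-1-semialdehyde aminomutases GSA2 (AT3G48730) and GSA1 (AT5G63570), which make aminolevulinic acid, rose from 17.1 ± 1.97 to 58.3 ± 5.30 CPM and from 8.30 ± 1.502 to 27.9 ± 1.43 CPM. GUN5 (AT5G13630), the H subunit of magnesium chelatase, rose by 1.29 ± 0.23 on the log2 scale, and protochlorophyllide oxidoreductase B (PORB, AT4G27440) from 97.5 ± 14.8 to 224 ± 46.0 CPM. The 2 that fell were HEMA2 (-0.73 ± 0.21) and ferrochelatase 1 (FC1, -0.82 ± 0.24), which makes haem, and without wild-type replicate 1, 0 fell and 14 rose. The adjusted p of the list was 9.25e-09 with camera, and 0.190 with an estimated correlation.

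Of 22 genes of the plastid transcription machinery, the nuclear-encoded partners of the plastid RNA polymerase, 16 rose and 0 fell (18 and 0 when adjusted over the list alone). The largest changes were in HMR (AT2G34640) with 1.87 ± 0.31, FSD2 (AT5G51100) with 1.85 ± 0.30 and PTAC2 (AT1G74850) with 1.51 ± 0.22, and FLN1 (AT3G54090) went from 2.07 ± 0.0448 to 5.84 ± 1.22 CPM. Camera gave an adjusted p of 3.72e-11, which became an adjusted p of 0.0908 with an estimated correlation, and fry gave 0.00248. Among 31 nuclear genes for plastid ribosomal proteins 15 rose and 1 fell (18 and 1 when adjusted over the list alone). PRPL1 (AT3G63490) rose from 23.58 ± 2.102 to 77.9 ± 17.83 CPM, with 11.7% of its exon bases in another gene, and PRPL3 (AT2G43030) from 34.4 ± 5.70 to 87.4 ± 25.4 CPM, whereas PRPS1 (AT5G30510) fell from 59.9 ± 1.71 to 22.2 ± 0.836 CPM. The camera call (adjusted p = 1.56e-06) had an adjusted p = 0.243 with an estimated correlation. Among 17 light signalling and chloroplast regulators 5 rose and 1 fell (7 and 1 when adjusted over the list alone). The count was 3 in all without wild-type replicate 3, and the fall of BBX21 (AT1G75540, -0.56 ± 0.18) was called with all 6 libraries and without pp7l-1 replicate 2, while 0 fell with any other library left out. GUN1 (AT2G31400), a plastid protein of signalling to the nucleus, rose from 9.38 ± 1.97 to 33.9 ± 6.48 CPM, and GLK1 (AT2G20570) and PHYB (AT2G18790) rose by 1.03 ± 0.19 and 1.01 ± 0.19 on the log2 scale. Here camera gave an adjusted p of 0.0108, and an adjusted p of 0.190 with an estimated correlation.

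In the light-harvesting antenna 0 of 21 genes passed with edgeR, and 0 also when adjusted over the list alone. At an unadjusted p under 0.05 there were 5, DESeq2 called 3 higher, limma voom 0 or, with sample quality weights, 3 higher, and edgeR 5 higher when scaled on library size alone and 1 higher without wild-type replicate 2. The most abundant were LHCB1.5 (AT2G34420) at 7563 ± 947 and 5999 ± 962 CPM, all of whose exon bases lie in other counted genes, and LHCB1.3 (AT1G29930) at 6041 ± 1101 and 7624 ± 1512 CPM. Log2 fold changes in the list lay between -0.61 and 0.65, with a median of 0.12 (camera adjusted p = 0.420). Of 34 nuclear genes for photosystem and electron transport subunits 3 rose and 3 fell, the same when adjusted over the list alone (camera adjusted p = 0.724). PSAD2 (AT1G03130) rose by 1.07 ± 0.28 and PSBR (AT1G79040) had a log2 fold change of -0.92 ± 0.30. With 1 library fewer, 0 genes were called without wild-type replicate 1, 1 without pp7l-1 replicate 1, and 2 without wild-type replicate 3 or pp7l-1 replicate 3. PSBR also did not pass without pp7l-1 replicate 2 (adjusted p = 0.0616), when 1 gene fell. In the Calvin-Benson cycle 4 of 19 rose and 1 fell (7 and 1 when adjusted over the list alone). Transketolase TKL1 (AT3G60750) rose by 1.12 ± 0.23, and the small Rubisco subunit RBCS2B (AT5G38420) had a log2 fold change of -1.40 ± 0.27. The count was 2 without wild-type replicate 1, 3 without wild-type replicate 3 and 11 without pp7l-1 replicate 2, and DESeq2 called 8. Its camera call (adjusted p = 0.0193) had an adjusted p of 0.618 with an estimated correlation, 0.125 with fry, 0.0719 without wild-type replicate 3 and 0.0699 without pp7l-1 replicate 1.

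Of 26 tested genes for the plastid-encoded polymerase, ribosomal proteins and other housekeeping functions 18 rose and 0 fell (21 and 0 when adjusted over the list alone), with a median log2 fold change of 1.32. The polymerase genes rpoB, rpoC1 and rpoC2 rose by 1.83 ± 0.24, 1.88 ± 0.25 and 1.78 ± 0.26. The ribosomal protein genes rps19 and rps3 had the highest values, 2.43 ± 0.39 and 2.39 ± 0.38, from 18.1 ± 3.35 to 97.3 ± 75.7 CPM and from 69.3 ± 11.3 to 362 ± 264 CPM, which were 1.59 and 1.62 without pp7l-1 replicate 3. Camera gave an adjusted p of 4.15e-12, and an adjusted p of 0.243 with an estimated correlation. Of 27 genes for photosystems, the cytochrome complex and Rubisco 5 rose and 5 fell (8 and 5 when adjusted over the list alone). petN fell from 2021 ± 767 to 646 ± 206 CPM and psbI from 2452 ± 1004 to 900 ± 297 CPM, while psbB rose from 4710 ± 970 to 11268 ± 1409 CPM. The test gave psbA a log2 fold change of -1.45 ± 0.60 (adjusted p = 0.0948) and rbcL one of 0.62 ± 0.48 (adjusted p = 0.386), so neither passed. The median was -0.37, or 0.11 when scaled on library size alone, and the camera adjusted p was 0.973. Without wild-type replicate 1, 0 rose and 2 fell, without wild-type replicate 2, 2 rose and 4 fell, without wild-type replicate 3, 5 rose and 1 fell, without pp7l-1 replicate 1, 6 rose and 2 fell, and without pp7l-1 replicate 2, 8 rose and 5 fell. psbB did not pass without wild-type replicate 1 (adjusted p = 0.110), nor psbI without wild-type replicate 3 (adjusted p = 0.0555).

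**Figure D4:**
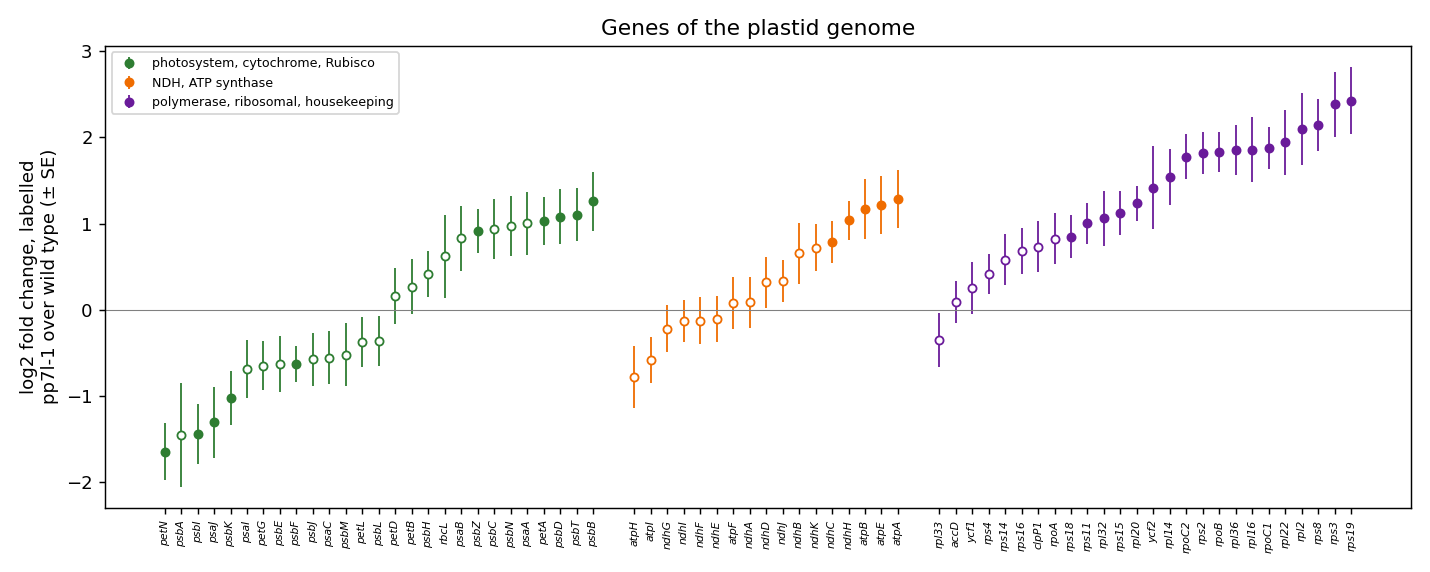
Log2 fold change (libraries labelled pp7l-1 over wild type, ± standard error, n = 3 and 3) of tested genes of the plastid genome in 3 classes, with filled points for genes past the test over all genes. The polymerase, ribosomal and housekeeping genes reach 2.43 in rps19 (1.59 without pp7l-1 replicate 3), and the photosystem class runs from -1.65 in petN to 1.26 in psbB.

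Of 17 plastid genes for the NDH complex and ATP synthase 5 rose and 0 fell (6 and 0 when adjusted over the list alone; camera adjusted p = 0.129). ndhH rose by 1.04 ± 0.23 and atpA by 1.28 ± 0.33 on the log2 scale. Without wild-type replicate 1 or wild-type replicate 3 the count was 1, without wild-type replicate 2 or pp7l-1 replicate 3 it was 2, and without pp7l-1 replicate 2 the camera adjusted p was 0.0257. atpA did not pass without wild-type replicate 1 (adjusted p = 0.0802) or wild-type replicate 3 (0.0537). Of 58 tested mitochondrial genes 19 rose and 1 fell (22 and 2 when adjusted over the list alone; 13 in all without wild-type replicate 1). The camera adjusted p of 3.74e-06 was an adjusted p of 0.253 with an estimated correlation.

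Of 10 tested genes of the anthocyanin and flavonoid pathway 6 rose and 0 fell, 7 and 0 when adjusted over the list alone. The glucosyltransferase UF3GT (AT5G54060) had 2 counts in the wild type and 53 in the libraries labelled pp7l-1, a ratio of 24.1 (exact 95% interval 6.34 to 204). Dihydroflavonol reductase (DFR, AT5G42800) rose from 0.206 ± 0.0750 to 3.26 ± 0.941 CPM, TT19 (AT5G17220) by 2.94 ± 0.46 (3.93 without wild-type replicate 3) and LDOX (AT4G22880) by 2.87 ± 0.43 on the log2 scale. The camera adjusted p was 2.94e-07, and an adjusted p = 0.106 with an estimated correlation, with 0.00426 from fry.

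Of 16 tested heat shock genes 12 fell and 0 rose (13 and 0 when adjusted over the list alone), with a median log2 fold change of -1.45, or -2.19 without pp7l-1 replicate 1. The heat shock factor HSFA7A (AT3G51910) fell from 16.0 ± 8.13 to 3.04 ± 2.13 CPM (log2 fold change -2.45, or -3.14 without pp7l-1 replicate 1) and the chaperone HSP90.1 (AT5G52640) from 58.6 ± 29.1 to 14.1 ± 8.12 CPM. ROF2 (AT5G48570) at 63.2 ± 41.8 and 17.37 ± 14.9 CPM and HSP23.6 (AT4G25200) at 5.34 ± 3.97 and 1.59 ± 1.17 CPM passed with edgeR (adjusted p = 0.0231 and 0.0244), but their groups overlapped. DESeq2 did not call them (0.201 and 0.247), nor did voom with quality weights or edgeR without wild-type replicate 1 or 2, and ROF2 also did not pass without pp7l-1 replicate 2 and HSP23.6 without pp7l-1 replicate 3. With edgeR the log2 fold changes of ROF2 and HSP23.6 were -1.88 and -1.85. They were -2.80 and -2.50 without pp7l-1 replicate 1 (adjusted p = 0.00295 and 0.0119), and -1.34 and -1.19 without wild-type replicate 1. Members of this list varied together between libraries, with an estimated correlation of 0.853. Camera gave an adjusted p of 2.61e-06 with the preset correlation and 0.410 with an estimated one, and fry gave 0.134. The count of calls was 5 without wild-type replicate 1 and 7 without wild-type replicate 2, pp7l-1 replicate 2 or pp7l-1 replicate 3, and DESeq2 called 7. Of 17 oxidative and mitochondrial stress genes 2 rose and 3 fell (2 and 4 when adjusted over the list alone; camera adjusted p = 0.530). Its median was -0.14, or 0.27 when scaled on library size alone. The ferritin gene FER1 (AT5G01600) fell from 106 ± 25.5 to 26.5 ± 5.20 CPM, ZAT10 (AT1G27730) fell by 1.61 on the log2 scale, the mitochondrial stress marker UPOX (AT2G21640) rose from counts of 0, 4 and 0 to 20, 14 and 21, so that without wild-type replicate 2 the wild type had 0, and catalase 3 (CAT3, AT1G20620) rose from 208 ± 35.6 to 633 ± 48.4 CPM. Of 20 abscisic acid, salt and cold response genes 6 rose and 3 fell (7 and 4 when adjusted over the list alone; camera adjusted p = 0.341). The falls were not called without wild-type replicate 1, where 0 fell, and without wild-type replicate 2, 4 rose and 1 fell. Without pp7l-1 replicate 1, 7 rose and 1 fell, and DESeq2 called 6 higher and 0 lower. The median of this list was -0.08 and its mean 0.24, so the 2 differ in sign, and the median was above 0 without wild-type replicate 1 (0.06), pp7l-1 replicate 2 (0.10) or pp7l-1 replicate 3 (0.03). ADH1 (AT1G77120) rose by 2.49 ± 0.37, the dehydrin RAB18 (AT5G66400) by 2.01 ± 0.42 and P5CS1 (AT2G39800), for proline synthesis, by 1.54 ± 0.25 on the log2 scale. In the defence list 1 of 5 tested genes rose, SID2 (AT1G74710), for salicylic acid synthesis, by 1.00 ± 0.22 (also when adjusted over the list alone; 1 other fell without pp7l-1 replicate 3; camera adjusted p = 0.568). Of 9 clock genes 1 fell, PRR7 (AT5G02810), by 0.51 on the log2 scale with an adjusted p of 0.0418, and 0 when adjusted over the list alone (camera adjusted p = 0.531). Its call was lost with any of the 6 libraries left out (adjusted p between 0.0830 and 0.116).

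Transposable element genes were examined because relatives of PP7L with a plant mobile domain act in transposon silencing. Of 67 genes with a transposon word in their product name 11 could be tested. Of these, 0 passed with edgeR, 0 when adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 with DESeq2. With limma voom or without pp7l-1 replicate 2, 1 passed, which was lower. The share of called-higher genes was 0% against 10.65% among all tested genes (Fisher's exact p = 0.620, two-sided), and the share of called-lower genes 0% against 11.3% (p = 0.625). With 11 genes, chosen by words in product names, this comparison cannot exclude a difference or stand for transposable elements as a class. Of the list 9 members had a log2 fold change above 0, with a median of 0.26. Camera gave an adjusted p of 0.420, while fry gave 0.0168, on balance towards higher. Of 4 loci known to be silenced in wild-type plants 3 were in the tables and 0 had enough counts to be tested. SDC had 11 counts in the wild type and 21 in the libraries labelled pp7l-1, QQS 4 and 36, and FWA 1 and 3. In the silencing machinery 2 of 10 genes rose and 0 fell, also when adjusted over the list alone, the DNA methyltransferase MET1 (AT5G49160) from 3.48 ± 0.374 to 9.01 ± 0.239 CPM and the remodeller DDM1 (AT5G66750) from 1.32 ± 0.0873 to 3.21 ± 0.0740 CPM. The camera call (adjusted p = 0.0333) had an adjusted p of 0.243 with an estimated correlation, 0.0746 without wild-type replicate 2 and 0.0774 without pp7l-1 replicate 3.

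Of 13 cell division genes 5 rose and 0 fell (9 and 0 when adjusted over the list alone), with PCNA1 (AT1G07370), the clamp of DNA polymerase, at 2.07 ± 0.857 and 4.28 ± 0.779 CPM and the cyclin CYCA1;1 (AT1G44110) at 2.89 ± 0.658 and 5.31 ± 0.337 CPM. The camera call (adjusted p = 0.00353) had an adjusted p of 0.243 with an estimated correlation. The count was 0 without wild-type replicate 3, 2 without pp7l-1 replicate 1 and 3 without wild-type replicate 1, wild-type replicate 2 or pp7l-1 replicate 3, and DESeq2 called 2. PCNA1 did not pass without wild-type replicate 1 (adjusted p = 0.0563), wild-type replicate 3 (0.0834) or pp7l-1 replicate 1 (0.0914), nor CYCA1;1 without wild-type replicate 3 (0.0569). Of 5 DNA damage genes 3 rose and 0 fell, also when adjusted over the list alone, with GMI1 (AT5G24280) up by 1.94 ± 0.27 and the ribonucleotide reductase subunit TSO2 (AT3G27060) from 11.8 ± 0.979 to 27.6 ± 5.63 CPM (camera adjusted p = 0.00903, and an adjusted p = 0.190 with an estimated correlation).

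Markers of cell types were included because whole seedlings were read. Of 9 tested root markers 5 fell and 2 rose (6 and 2 when adjusted over the list alone). The Casparian strip gene CASP1 (AT2G36100) fell from 19.4 ± 2.93 to 6.82 ± 1.91 CPM, the root hair gene PRP3 (AT3G62680) from 8.07 ± 1.85 to 3.81 ± 0.953 CPM and the iron transporter IRT1 (AT4G19690) by 1.08 on the log2 scale, while the transcription factor SHR (AT4G37650) rose from 0.782 ± 0.382 to 2.80 ± 0.719 CPM. Without wild-type replicate 2, 3 fell, and IRT1 did not pass (adjusted p = 0.0527), and without wild-type replicate 1, 1 rose. The median of the list was -0.79. Camera gave an adjusted p of 0.123, and 0.0287 without wild-type replicate 1. Of 4 shoot meristem and leaf primordium markers 2 rose, also when adjusted over the list alone, AS1 (AT2G37630) by 1.22 ± 0.28 and KNAT1 (AT4G08150) by 0.89 ± 0.29 (camera adjusted p = 0.0550). The count was 1 without wild-type replicate 1, wild-type replicate 2 or pp7l-1 replicate 3, where KNAT1 did not pass (adjusted p = 0.115, 0.118 and 0.217), and camera gave 0.0195 without pp7l-1 replicate 2. AS1 shares 17.2% of its exon bases with another gene. Of 8 tested genes in the stomatal and guard cell list 1 rose, STOMAGEN (AT4G12970), from 2.65 ± 0.645 to 4.87 ± 1.68 CPM, and 0 when adjusted over the list alone (camera adjusted p = 0.438). A rise of this 1 gene does not show a change in these cells. The call was lost without wild-type replicate 2 (adjusted p = 0.101), wild-type replicate 3 (0.112) or pp7l-1 replicate 2 (0.135).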

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

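Tests added after the data were examined were the 3 that left out ribosomal DNA genes, all but nuclear protein-coding genes, or overlapping genes. They gave 3994, 3906 and 3354 genes and moved none of the counts over all genes by over 1.5 times. A mean of 5 CPM left 7974 genes to test and gave 2355 (1165 higher, 1190 lower, 805 over 2-fold). Library size alone gave 4493 higher, 759 lower and 3307 over 2-fold, because a shift of 0.41 in all genes was left in. With 1 library left out, the higher genes numbered 1274 to 2146, the lower 1384 to 2219, all together 2671 to 4365, and those over 2-fold 1782 to 2535. Of the 2671 called without pp7l-1 replicate 1, 2509 were also called with all 6 libraries. The other alternatives gave between 2792 (glmTreat) and 5252 genes (library size alone). The numbers of transposable element genes called were 2 with library size alone, 1 without a count filter, 1 with limma voom, 1 with voom quality weights, and 0 to 1 with 1 library left out. Camera called 0 lists with an estimated correlation, 13 without organelle genes, and 14 to 17 with 1 library left out. The cause of these differences was not tested, except that fewer genes or libraries entered. The replicate numbers did not pair the libraries. Same-numbered libraries had residual correlations of 0.1, -0.0280 and 0.0535, and pp7l-1 replicate 2 correlated best with wild-type replicate 3 (0.119). With the replicate block 4153 genes and 14 lists were called, the silencing machinery being lost (adjusted p = 0.0507), and psaJ and PSBR did not pass (0.0641 and 0.0756). The PP7L log2 fold change lay between 3.38 and 3.93 and passed in every alternative run. The plastid share fell by 7.25 to 11.3 percentage points and the mitochondrial share rose by 0.238 to 0.308 points with 1 library left out. A smaller share of psbA by itself raises the mitochondrial share. Of 109 named genes 80 kept their call and direction under all alternatives that tested them. Among those that did not were PSAD1, PSAF, FBA2, TIM, PIF3, atpE, atpB, COR15A, BRCA1, MCM2 and MCM5, taken by the rule, each of which rose with edgeR and lost its call in 1 or more alternatives. PP7, MAIL3 and LHCB1.5, which did not pass, switched sign in some, and 0 genes past the threshold did. In 108 of 2206 comparisons a call was lost. Depth limits low genes most, since 15226 genes of the tables had too few counts to be tested.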

Other observations

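Tests on the 3 lists of root and seed genes, on the 23 product families, on promoter words and on neighbouring genes were chosen after the main results were seen. Bounds that decide them were written before the tests of a smaller share of root, of dry seeds and of promoter words were run, and after the values were seen for the spread within the root list. None was written for the product families or for neighbouring genes.

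Among 23 families taken from product names, several held more or fewer called genes than the rest of the tested genes. Of 54 tested genes with lipid transfer protein in their product name 23 were lower (42.6%, against 11.3% of all tested genes, Fisher's exact adjusted p = 2.15e-07) and 8 higher. Such names include that of a superfamily shared with bifunctional inhibitors and seed storage 2S albumins, as for AT4G12510, so these genes need not be lipid transfer proteins. Extensin or proline-rich proteins of the cell wall had 33 of 126 lower (adjusted p = 6.43e-05) and 13 higher, arabinogalactan proteins 12 of 36 lower (0.00176) and 3 higher, aquaporins 8 of 24 lower (0.0127) and 3 higher, WRKY factors 10 of 36 lower (0.0172) and 2 higher, and small heat shock proteins 7 of 24 lower (0.0404) and 1 higher. Peroxidases had 14 of 46 lower (0.00176) and 10 higher (21.7%, against 10.6% of all tested genes, adjusted p = 0.0641). Of 37 genes annotated as late embryogenesis abundant 13 were lower (adjusted p = 0.000787) and 5 higher. Product names need not pick the same genes as the list of dry seed transcripts described below, of which 5 of 5 tested were higher. EM6 and RAB18 of that list, for example, are named a stress induced protein and a dehydrin. The falls in this family therefore do not speak to the dry seed transcripts. Pentatricopeptide repeat proteins, which act on organelle RNA, had 3 of 170 lower (adjusted p = 6.58e-05 for few lower). Their 21 higher genes (12.4%) were near the 10.6% of all tested genes (adjusted p = 0.673). Tetratricopeptide proteins had 7 of 201 lower (0.000787) and 36 higher (0.00726). F-box proteins had 6 of 139 higher (0.0374 for few higher) and 9 lower (6.47%, against 11.3% of all tested genes, adjusted p = 0.166), so calls were few in both directions. Higher genes were more frequent among UDP-glycosyltransferases (23 of 87, adjusted p = 0.000320, with 5 lower), aminoacyl-tRNA synthetases (15 of 51, 0.00108, with 5 lower), pectin lyase and invertase families (19 of 68, 0.000550, with 7 lower) and cytochromes P450 (24 of 124, 0.0125, with 19 lower). Among gene types of the annotation, 18 of 73 tested genes typed as ncRNA were lower (adjusted p = 0.0139) and 2 higher (0.0520), and of 52 snoRNA genes 0 were higher (0.0217 for few higher) and 9 lower (0.545), all with edgeR. Members of a family can share reads, and they are not independent genes. A list of differentiated root cell genes was chosen after the main results were seen, where PIP2;4 was already among the largest falls. In the same libraries 12 of its 17 tested genes were lower, with a median of -1.25. Of those lower genes 3 were counted above as extensin or proline-rich (LRX1, LRX2, PRP1), 2 as aquaporins (TIP2;3, PIP2;4), 1 as a peroxidase (AT4G26010) and 1 as a cytochrome P450 (CYP86A1). Outside that list 30 of 123 extensin or proline-rich genes, 6 of 22 aquaporins, 13 of 45 peroxidases and 18 of 123 cytochromes P450 were lower, and it held 0 of the lipid transfer and arabinogalactan genes. Whether other members of these families are root genes was not tested.

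The 50 nuclear genes with the strongest falls lay next to each other more often than random sets. Of them 12 had another of the set within 3 tested genes, against a median of 0 and a maximum of 8 in 10000 random sets (permutation p = 1e-04, the smallest that number can give). For the 50 strongest rises the count was 4 (permutation p = 0.0595). Of the 12, AIR1 with AT4G12555 and AT4G12543 with AT4G12545 were pairs on opposite strands that overlap and had near-equal counts, so the same reads may have been counted for both partners. With overlapping genes left out before the 50 were taken, 8 had a neighbour in the set, against a maximum of 10 in the random sets (permutation p = 0.0016), and 2 of the rises (0.389). The groups of falls included FAP3 with AT1G53530, and AT5G46890 with AT5G46900 on chromosome 5. Both genes of the latter pair are named as members of the bifunctional inhibitor, lipid transfer protein and seed storage 2S albumin superfamily. Other groups were the snoRNAs AT3G08165 and AT3G50825 (chromosome 3, from 18893230 and 18893404), and 6 genes of chromosome 4, among them AT4G12510, AT4G12520 and AIR1 (AT4G12550, 41.2% of its exon bases in AT4G12555). Copies that share reads would add to such groups. A short sequence shared by the promoters was the only explanation tested for these falls as a set, and others stay open. Only protein-coding genes entered, and of falls within 3 tested genes of each other 1 was kept. Among 711 words of 8 bases compared in the 500 bases before these genes, 1 was most enriched on chromosomes 1, 3 and 5. This word occurred there before 3 of 23 of them. On chromosomes 2 and 4 it occurred before 0 of 16 (Fisher's exact p = 1), which at this number leaves the explanation open.

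PP7L reads were higher in the libraries labelled pp7l-1. The 14 tested neighbours within 20 kb had a median log2 fold change of -0.23, and each was below PP7L. This argues against a change shared by that whole stretch of chromosome 5. AT5G10910 and AT5G10920 beside PP7L rose by 1.47 and 1.07 and passed with edgeR (adjusted p = 0.00558 and 0.00375). ER and AT5G10830 had -1.01 and -0.62 (adjusted p = 0.0178 and 0.0466). A change that reaches only the genes beside PP7L is therefore not excluded. Reads of an overlapping gene are argued against by 0% of shared exon bases. It also stays open that an inserted sequence in the mutant may start transcription within the gene, that the gene is itself expressed more, or that the labels of the groups as a whole are exchanged, none of which counts over whole genes separate.

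In the same libraries 7 of 9 seed storage and embryo markers rose, and 5 of 9 root markers fell while 2 rose, a list that camera did not call. Dry or ungerminated seeds among the seedlings may account for part of the first and stay open, since the summed level of 10 late embryogenesis transcripts was 4.43-fold higher and did not overlap between groups (2.83 to 4.64 CPM in the wild type), with 5 of 5 tested ones higher, of which EM6 and RAB18 are also in the fixed lists, but EM1 at 0.0236 and 0.0505 CPM, and with storage protein sums (3.86 to 6.31 CPM in the wild type, 128, 96.5 and 31.7 CPM in pp7l-1 replicates 1 to 3) that did not move in step with the late embryogenesis sums (19.7, 14.8 and 15.8 CPM). A smaller share of root as the only cause of the lower root genes stays open, since of 17 tested genes of differentiated root cells 6 lay more than 3 standard errors from their median of -1.25, with PIP2;4, TIP2;3 and PRP1 below it and PHT1;1, RBOHC and ESB1 above it, but ESB1 has 84.3% of its exon bases in another gene, and with overlapping genes left out only 2 lay above, under the 3 that the bound asked for. As part of the cause it was not separated from a change within roots either, because the root tip list (1 of 6 tested genes higher and 1 lower, 1.54 above the differentiated root list in median log2 fold change, permutation p = 0.00672) holds 4 genes that shoots also express. A biological explanation by genotype was not tested and stays open.

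Of 26 tested plastid housekeeping genes 18 rose, while the share of psbA was lower in each library labelled pp7l-1 than in any of the wild type. Genomic DNA in the libraries labelled pp7l-1 would add the same number of reads per kilobase to every gene, and is argued against because the gain rose with the wild-type level across 26 genes (Spearman rho = 0.593, permutation p = 0.00155, across genes, which are not independent replicates). Fewer psbA reads leaving room for others is argued against by the median of 1.33 that the list kept when libraries were scaled on nuclear genes alone. A change of plastid transcription or RNA turnover with the genotype is therefore a hypothesis that these tables leave open, found and examined on the same data, and a difference in how plastid RNA without a poly(A) tail entered the libraries was not tested.

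Splits of the 6 libraries into 3 and 3 number 10, the real one included, too few to give a share under 0.05. The real split gave 3972 genes and the highest other split 0, with 1 of the 10 splits reaching the real count. Each other split put both genotypes in each of its groups, so a genotype difference added to the spread within groups. Few calls were likely there for that reason, and the 0 does not measure how many calls arise by chance. For transposable element genes the real split gave 0, as did the other splits (10 of 10). For gene lists the real split gave 15 by camera with the preset correlation and the other splits 4 to 12 (1 of 10 splits reached 15), although those splits called 0 genes. Their groups still differed in the mix of genotypes, so these list counts are not those of data without a difference.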
